A study of Homo sapiens with 42 samples.

How the data were processed

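RNA was sequenced from OCI-Ly3 and TMD8, established human cell lines of activated B cell-like diffuse large B-cell lymphoma, a lymphoma type that often depends on the protease MALT1. In a first experiment both lines received compound 3, described in the series title and design as a covalent MALT1 inhibitor, at 100 nM or its solvent DMSO, for 8 h or 24 h. It holds 24 libraries in 8 groups of 3. In a second experiment both lines were infected with a lentivirus carrying MALT1 hairpin 1, MALT1 hairpin 2 or a non-targeting hairpin, and it holds 18 libraries in 6 groups of 3. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

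Libraries were made with a stranded kit that selects mRNA, per the labels' protocols. Reads were aligned with STAR (version not given) to the human genome hg19, per the submitters' processing notes. The read counter, its version and its strand setting are not given in the sources used here. The deposited values are CPM, made by the authors, and the file names call the gene models RefSeq. Each of the 42 files lists 23250 rows by a running number and a CPM, and the files do not pair the row numbers with gene names. Each result is therefore about numbered rows, and no row was named from its place in an annotation. For the same reason the level of MALT1 and 28 gene lists fixed before the data were examined are not reported. Rows that share reads with a near-identical copy or an overlapping gene could not be set apart.

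The rows of each library summed to less than the full scale of CPM, so the authors divided by a total that is larger than the reads in the rows. Every value was a whole multiple of the smallest value of its library (100% of the values within 1e-06 of a whole number), which recovers the reads. The totals that these steps imply were 32.3 to 40.9 M reads a library with the compound and 20.5 to 24.5 M reads in the knockdown. Of these, 71.9% to 79.6% and 73.6% to 79.3% lay in the rows. A CPM of 1 thus stood for 32.3 to 40.9 reads in the first experiment and 20.5 to 24.5 in the second. Counting error is only part of the error, and the spread between libraries was used for every test. No files were identical: the chi-square per degree of freedom of the 42 pairs of libraries within groups ran from 1.74 to 103 (expected 1 for sampling noise alone), so every library was counted as a sample. Knockdown pairs went down to 1.74, against 12.2 at the lowest with the compound, so knockdown replicates may be closer to technical ones. Counts of called rows are thus not directly comparable between the experiments. The rows were taken to be in the same order in both experiments. Mean CPM per row of the control groups had a Spearman correlation of 0.966 to 0.967 between the experiments within a line, against 0.923 to 0.925 between lines.

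The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with 1 group-means model for each experiment, eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment over the rows tested. Rows with a CPM of at least 1 in at least 3 libraries of the experiment were tested, 12589 with the compound and 12303 in the knockdown, 12038 of them in both. A row is called at a two-sided adjusted p below 0.05. Fold changes are on the log2(CPM + 1) scale, which understates changes of rows near the floor. All libraries of an experiment share 1 estimate of the spread per row. Because the unit is CPM, count tests served as alternatives only, on the recovered reads: edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test, size factors).

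Called with both hairpins means called against the non-targeting control with each of them, in the same direction. These sets of rows were tested in the compound experiment of the same line with camera, at a preset correlation of 0.01 between rows and again with an estimated correlation, and with fry, adjusted over the pair of sets in each comparison. The value of fry moves slightly with the order of the groups in the model, which was alphabetical. Each set was chosen in the other experiment, on other libraries. Sets with fewer than 10 rows were not tested. Comparisons of both hairpins with the same controls share chance values, and 100 simulations of unchanged groups and controls gave a level that this sharing produces. They drew normal values around the mean of each line, with 1 spread per row for all groups and, chosen after seeing the data, with each group's own spread per row, with and without OCI-Ly3 non-targeting replicate 1. Rows were drawn independently, so chance values shared by many rows of a library were not simulated. The highest simulated counts are thus no upper bound. Correlations of fold changes are across rows, which are not independent replicates, and describe the data without a test.

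The rule for single rows, fixed before the data were examined, takes called rows with a mean CPM of at least 5 over the 6 libraries compared and no overlap between treated and control libraries, by the largest log2 fold change. Since the rows carry no gene names, only the 2 most raised and the 2 most lowered rows of OCI-Ly3 at 24 h are printed, a restriction set after the data were seen.

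Replicate numbers recur across groups. Whether they pair libraries was checked by the correlation across rows of same-numbered libraries' deviations from their group means, before any fits were compared. All correlations exceeded 0.1 for DMSO and compound 3 in OCI-Ly3 at 8 h (0.715 to 0.808), OCI-Ly3 at 24 h (0.378 to 0.599) and TMD8 at 8 h (0.75 to 0.921), where each of the 6 libraries correlated best with its own number. The same held between DMSO at 8 h and at 24 h in OCI-Ly3 (0.318 to 0.699). The fit with the replicate number as a block is given beside those results where it changes the call or the count by over 1.5 times. The numbers in TMD8 at 24 h, between the DMSO times of TMD8 and in the knockdown failed the check.

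Alternatives fixed before the data were examined were a pseudocount of 0.25, no filter (19553 and 17778 rows), a minimum CPM of 5 (10473 and 10372 rows), rescaling by the median ratio, quantile normalization, the replicate block, edgeR, DESeq2, robust eBayes, a fit of the same cell line alone, and leaving out each library in turn. Alternatives without OCI-Ly3 non-targeting replicate 1, without the TMD8 8 h libraries numbered 1, with the block but without the TMD8 24 h libraries, with a block shared by both times of a line, and with the block in the compound experiment alone were chosen after seeing the data. So were all alternatives for the DMSO time comparison and the correlations, those of the set tests other than the estimated correlation and fry, and the leaving out of libraries for single rows.

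The scripts were tested on 5 simulated data sets for each of 4 comparisons, each with 200 changed rows drawn from the real means and library sizes. Of changes of 1.5-fold, 2-fold and 4-fold, 25.4%, 71% and 91.5% were recovered for compound 3 at 24 h in OCI-Ly3 and 25.1%, 69% and 91.8% in TMD8. For hairpin 1 they were 53.4%, 80.6% and 95.5% in OCI-Ly3 and 48.4%, 78.2% and 91.5% in TMD8. At most 24 false calls arose in a data set.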

Results

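Transcript levels were measured in 42 libraries of the lymphoma lines OCI-Ly3 and TMD8, in 14 groups of 3. With the compound, 23.3 to 31.6 M reads a library lay in the 23250 rows, and in the knockdown 15.8 to 19.4 M reads. Each row stands for a gene model that the files number but do not name, so changes are described by how many rows moved, by how much, in which cells, and whether sets of rows moved together. MALT1 itself is among the unnamed rows, and its level, the usual check of a knockdown, is not reported.

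The first principal component separated OCI-Ly3 from TMD8 in both experiments, with 82.3% of the variance in the compound experiment and 84.3% in the knockdown. Replicates differed little beside this, with exceptions. OCI-Ly3 non-targeting replicate 1 lay more than 1 log2 unit from the mean of the other two controls in 1168 rows, against 171 and 147 rows for those controls and at most 50 for any other knockdown library. The TMD8 8 h libraries numbered 1 did so in 544 rows with DMSO and 556 with compound 3, against 55 to 141 rows for the other TMD8 libraries of that time.

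Compound 3 for 8 h lowered 5 rows in OCI-Ly3 and raised none (limma, adjusted p below 0.05). Their median log2 fold change was -1.09, the most lowered row reached -1.77, and 3 fell at least 2-fold. Of the 5, 3 also fell at 24 h, against 0.00596 expected of independent lists. Row 19825 held 534 ± 98 CPM with DMSO and 291 ± 66 CPM with compound 3 (SD, n = 3 each), a log2 difference of -0.89 (SE 0.17) with a limma adjusted p of 0.0816, not called. At an unadjusted p below 0.05, limma gave 163 rows, fewer than the share of 0.05 that unchanged rows would give. With replicates blocked, 45 rows were called, 4 higher and 41 lower, the 5 among them, and row 19825 was called (limma adjusted p = 5.36e-05). The count was 2 with edgeR, 11 with DESeq2, 3 after quantile normalization, 8 without a filter, 0 in a fit of OCI-Ly3 alone, and 8 without the TMD8 8 h libraries numbered 1. It was 2 without DMSO replicate 3 and 1 without compound replicate 2 or 3.

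At 24 h compound 3 raised 82 rows in OCI-Ly3 and lowered 15 of the 12589 tested. Of these, 30 rose and 4 fell at least 2-fold, with median log2 fold changes of 0.88 and -0.65. The raised rows were weakly expressed, at a median of 8.11 CPM against 18.5 CPM for the lowered ones and 21.6 CPM over all rows. Row 2626 rose most, from 16.0 ± 5.8 to 160 ± 67 CPM (SD, n = 3 each; log2 fold change 3.24, SE 0.46; limma adjusted p = 0.000919). Row 15831 rose from 1.68 ± 0.12 to 11.6 ± 1.2 CPM (log2 fold change 2.22, SE 0.45; limma adjusted p = 0.0153). Row 5587 fell from 25.8 ± 4.5 to 11.1 ± 2.1 CPM (log2 fold change -1.15, SE 0.15; limma adjusted p = 0.000408), and row 19825 from 484 ± 37 to 290 ± 9.7 CPM (log2 fold change -0.73, SE 0.17; limma adjusted p = 0.0468). The call of row 19825 ended in 7 of 10 alternative settings (adjusted p 4.74e-05 to 0.131) and without any 1 of the 6 libraries, and that of row 15831 without any library but compound replicate 1 (adjusted p up to 0.116). With replicates blocked, 1142 rows were called, 678 higher and 464 lower, all 97 among them. edgeR called 56 rows, DESeq2 186 (133 higher, 53 lower) and a fit of OCI-Ly3 alone 32. Without DMSO replicate 1, 2 or 3 the count was 36, 58 or 50, and without compound replicate 2 or 3 it was 19 or 50.

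**Figure D1:**
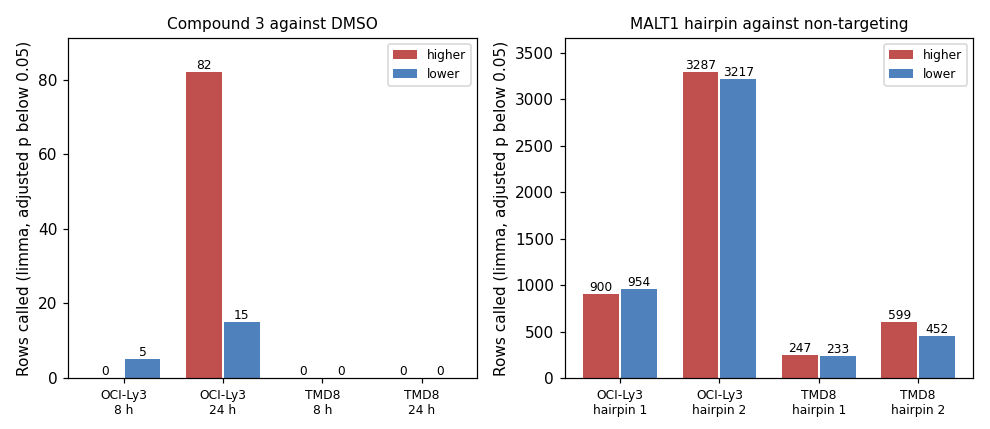
Number of rows called higher (red) or lower (blue) by limma at an adjusted p below 0.05, for compound 3 against DMSO (left) and for each MALT1 hairpin against the non-targeting hairpin (right), on separate scales. The compound counts reach 82 and 15 rows in OCI-Ly3 at 24 h, and the knockdown counts reach 3287 and 3217 rows with hairpin 2 in OCI-Ly3. All counts are from the fit without the replicate block. With the block, compound 3 in OCI-Ly3 gives 4 higher and 41 lower rows at 8 h, and 678 and 464 at 24 h.

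In TMD8, compound 3 changed no row past the threshold at either time. Row 2626, the most raised row of OCI-Ly3, held 64.2 ± 15 CPM with DMSO and 95.2 ± 16 CPM with compound 3 at 24 h (SD, n = 3 each), a log2 difference of 0.58 (SE 0.46; limma adjusted p = 1). Row 5587 held 31.3 ± 1.2 and 33.5 ± 1.1 CPM, a log2 difference of 0.10 (SE 0.15; limma adjusted p = 1). limma gave 131 rows at an unadjusted p below 0.05 at 8 h and 92 at 24 h, and both edgeR and DESeq2 called 0 at each time. Both limma counts lie below the share of 0.05 of the rows tested that unchanged rows would give. The test may thus be conservative, and these counts are no hint of change, nor do they show its absence. At 8 h, 2 rows were called lower with replicates blocked and 1 higher without a filter.

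Whether the lines respond differently was tested by the difference between their compound effects. At 24 h, 3 rows differed: 1 moved higher in OCI-Ly3 than in TMD8 by a log2 difference of 0.73, and 2 moved lower, with a median of -1.40. Row 5587 was among them, with a difference of -1.25 (SE 0.21; limma adjusted p = 0.0404). Row 2626 differed by 2.66 (SE 0.65), which was not called (limma adjusted p = 0.354). With replicates blocked its limma adjusted p was 8.09e-06 and 261 rows differed at 24 h, but the TMD8 24 h numbers do not pair. At 8 h, 1 row differed, by -1.38, and 2 did with replicates blocked. edgeR called 0 rows at both times and DESeq2 called 11 at 24 h and 0 at 8 h. The 24 h count fell to 1 without OCI-Ly3 DMSO replicate 1 or 3, OCI-Ly3 compound replicate 2, or any 1 of the 6 TMD8 24 h libraries. The 8 h count became 0 with a pseudocount of 0.25, 2 without a filter, and 0 without OCI-Ly3 DMSO replicate 1, OCI-Ly3 compound replicate 2 or 3, or any TMD8 8 h library but DMSO replicate 2.

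Whether the effect grew with time was tested in the same way. The effect at 24 h differed from that at 8 h in no row of either line by limma. In OCI-Ly3, 336 rows had an unadjusted p below 0.05, edgeR called 0 and DESeq2 called 21, of which 20 were higher at 24 h. In TMD8, 70 rows had an unadjusted p below 0.05, and edgeR and DESeq2 called 0. The unadjusted counts of both lines lie below the share of 0.05 that unchanged rows would give. With replicates blocked, 179 rows differed in OCI-Ly3, 150 higher and 29 lower at 24 h. They include rows 2626, 15831 and 5587, with log2 differences of 3.17, 2.17 and -0.855 and limma adjusted p of 8.65e-07, 0.00345 and 0.00382, against 0.214, 0.722 and 0.436 without the block. Without a filter 4 rows did, and 1 without OCI-Ly3 24 h compound replicate 1. No row was called in the same direction in all 4 compound comparisons, by limma, edgeR or DESeq2, and 3 rows, all lower, had an unadjusted p below 0.05 in each.

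Cells in DMSO alone changed between 8 h and 24 h. In OCI-Ly3, 116 rows were higher and 285 lower at 24 h, and in TMD8 434 were higher and 467 lower. Row 2626 fell in both lines, from 72.8 ± 42 to 16.0 ± 5.8 CPM in OCI-Ly3 (SD, n = 3 each; log2 fold change -2.05, SE 0.46; limma adjusted p = 0.0192) and from 214 ± 100 to 64.2 ± 15 CPM in TMD8 (log2 fold change -1.64, SE 0.46; limma adjusted p = 0.036). With compound 3, row 2626 held 78.8 ± 52 CPM at 8 h and 160 ± 67 CPM at 24 h in OCI-Ly3. Row 5587 rose in OCI-Ly3 from 15.0 ± 3.6 to 25.8 ± 4.5 CPM (log2 fold change 0.76, SE 0.15; limma adjusted p = 0.00829). Across rows, the time changes of the lines had a Pearson correlation of 0.518 and shared no library. With replicates blocked across the times, 1356 rows were called in OCI-Ly3, 438 higher and 918 lower, the 401 among them. Without the block the count there was 873 with DESeq2, 258 with the stricter filter, 977 without the TMD8 8 h libraries numbered 1, 344 (161 higher, 183 lower) after quantile normalization, 70 or 635 without 8 h replicate 1 or 3, and 129, 139 or 183 without 24 h replicate 1, 2 or 3. In TMD8 it was 1488 with DESeq2, 359 without both 8 h libraries numbered 1, 175 without DMSO 8 h replicate 1, and 417, 333 or 484 without 24 h replicate 1, 2 or 3.

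In OCI-Ly3 the MALT1 hairpins called more rows than compound 3 did at 24 h in the main test. The experiments differ in the spread between libraries and in the share of simulated changes recovered. No test compared them, so the counts do not rank the treatments. Hairpin 1 raised 900 and lowered 954 of 12303 rows, and hairpin 2 raised 3287 and lowered 3217. At least 2-fold, 106 rose and 23 fell with hairpin 1, and 589 rose and 201 fell with hairpin 2. Row 2626 rose from 15.0 ± 11 CPM to 215 ± 13 CPM with hairpin 1 (SD, n = 3 each; log2 fold change 4.13, SE 0.44; limma adjusted p = 2.42e-05) and 356 ± 71 CPM with hairpin 2 (log2 fold change 4.83; limma adjusted p = 3.36e-07). Row 15831 rose from 2.32 ± 1.5 to 19.7 ± 3.3 and 32.0 ± 18 CPM, with log2 fold changes of 2.75 and 3.23 (SE 0.42; limma adjusted p = 0.000648 and 1.28e-05). Without non-targeting replicate 1 the log2 fold changes were 3.29 and 3.99 for row 2626 and 2.31 and 2.79 for row 15831, hairpin 1 first. Rows 5587 and 19825, lowered by the compound, rose with hairpin 2, by log2 fold changes of 1.23 (SE 0.35; limma adjusted p = 0.0075) and 0.72 (SE 0.17; limma adjusted p = 0.00227). Row 5587 held 16.3, 63.8 and 74.6 CPM and row 19825 held 382, 759 and 753 CPM in the control libraries. Without the first of these, which stands apart, the changes were 0.56 and 0.395, and row 5587 was not called in a fit of OCI-Ly3 alone (limma adjusted p = 0.0556). The hairpin 2 libraries also had fewer of their reads in the rows, 74.1% ± 0.6 (SD, n = 3) against 78.6% ± 0.63 for the controls. For hairpin 1, a fit of OCI-Ly3 alone called 384 rows, fewer than a fit of TMD8 alone, given below. Without hairpin 1 replicate 1, 2 or 3 the count was 1077, 997 or 935, and without control replicate 2 or 3 it was 3062 or 2797.

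Both hairpins called 1452 rows in the same direction in OCI-Ly3, 747 higher and 705 lower. Independent lists of these lengths would share 240 and 249. The change was further from 0 with hairpin 2 in 82.4% of the 1452, with medians of 0.51 and 0.81 for the raised and -0.39 and -0.65 for the lowered rows, hairpin 1 first. The fold changes of the hairpins correlated at 0.684 across rows with a covariance of 0.128. The control libraries had a median SD of 0.20 log2 units, against 0.08 and 0.12 for the hairpin libraries. Unchanged groups simulated with each group's own spread gave a higher correlation, 0.857, a covariance of 0.0445 and at most 311 rows called with both. Without non-targeting replicate 1, the observed values were 0.608, 0.0756 and 1445 rows, against 0.388, 0.00446 and at most 6 rows simulated. With 1 spread for all groups the simulation gave 0.501, 0.0113 and at most 1 row. All simulations drew rows independently, so these highest counts are no upper bound on what shared controls can give. Hairpin 2 against hairpin 1 directly called 2293 rows higher and 2485 lower, and 3126 in all with OCI-Ly3 alone. With 3 controls, no division leaves 2 libraries in each part, so part of the overlap may come from the controls they share. The number called with both was 2389 or 2196 without control replicate 2 or 3, and 886, 815 or 734 without hairpin 1 replicate 1, 2 or 3.

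In TMD8, hairpin 1 raised 247 rows and lowered 233, and hairpin 2 raised 599 and lowered 452. Few changed at least 2-fold: 2 rose and 14 fell with hairpin 1, and 21 rose and 32 fell with hairpin 2. Row 2626 held 427 ± 24 CPM in the controls, 535 ± 50 CPM with hairpin 1 and 744 ± 23 CPM with hairpin 2 (SD, n = 3 each), log2 differences of 0.32 and 0.80 that were not called (SE 0.44; limma adjusted p = 0.764 and 0.31). The hairpins called 219 rows in the same direction, 101 higher and 118 lower, against 12 and 8.56 expected of independent lists. Of the 219, hairpin 2 moved 50.2% further. The fold changes correlated at 0.512 with a covariance of 0.0261, against 0.44, 0.00455 and at most 1 row called with both in unchanged groups simulated with their own spread, and 0.499, 0.0112 and 0 rows with 1 spread for all groups. Of all reads, 74.9% ± 0.32 lay in the rows in the TMD8 controls, 77.5% ± 0.78 with hairpin 1 and 76.9% ± 0.66 with hairpin 2 (SD, n = 3 each). Hairpin 2 against hairpin 1 called 355 rows higher and 276 lower.

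The TMD8 counts depend on the OCI-Ly3 libraries that share the estimate of the spread. Without OCI-Ly3 non-targeting replicate 1, hairpin 1 called 1953 rows in TMD8, hairpin 2 called 2810, both called 951, and the hairpins differed in 1994. TMD8 fitted alone gave 2088, 2707 and 2012 for hairpin 1, hairpin 2 and their difference. Median-ratio rescaling turned the balance of directions for each hairpin, with 163 rows higher and 276 lower for hairpin 1 and 440 and 546 for hairpin 2. For both hairpins, where lowered rows already outnumbered raised ones, it gave 65 and 140. Quantile normalization gave 157 and 265 for hairpin 1 and 59 and 127 for both. Leaving out any 1 of the 6 TMD8 libraries gave 139 to 283 rows for hairpin 1. For hairpin 2 the count was 526 to 680 without any library but hairpin 2 replicate 1. For the difference of the hairpins it was 285 to 344 without any library but hairpin 2 replicate 1. The count with both was 89 to 145 without any control or hairpin 1 library.

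The hairpin effects differed between the lines. Because the level of MALT1 was not read, unequal knockdown cannot be told apart from a different response to it. The effect of hairpin 1 differed in 960 rows, 476 higher and 484 lower in OCI-Ly3, and that of hairpin 2 in 4920, 2289 higher and 2631 lower. Row 2626 rose further in OCI-Ly3 with each hairpin, by log2 differences of 3.80 (SE 0.62; limma adjusted p = 0.0028) and 4.03 (SE 0.62; limma adjusted p = 0.000128). Of the rows raised by both hairpins, 23 were raised in both lines, against 6.13 expected, and 9 of the 747 raised in OCI-Ly3 were lowered in TMD8. Of the rows lowered by both, 6 were lowered in both lines, against 6.76 expected. These overlaps use the TMD8 sets of 101 raised and 118 lowered rows. More rows were called there without OCI-Ly3 non-targeting replicate 1, and the overlaps were not counted with those. Across rows, fold changes of the same hairpin in the 2 lines correlated at 0.0993 and 0.111. For hairpin 1, rescaling gave 559 rows higher and 308 lower, and the count was 1778, 1489 or 1442 without OCI-Ly3 control replicate 1, 2 or 3 and 399 to 620 without any other library.

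**Figure D2:**
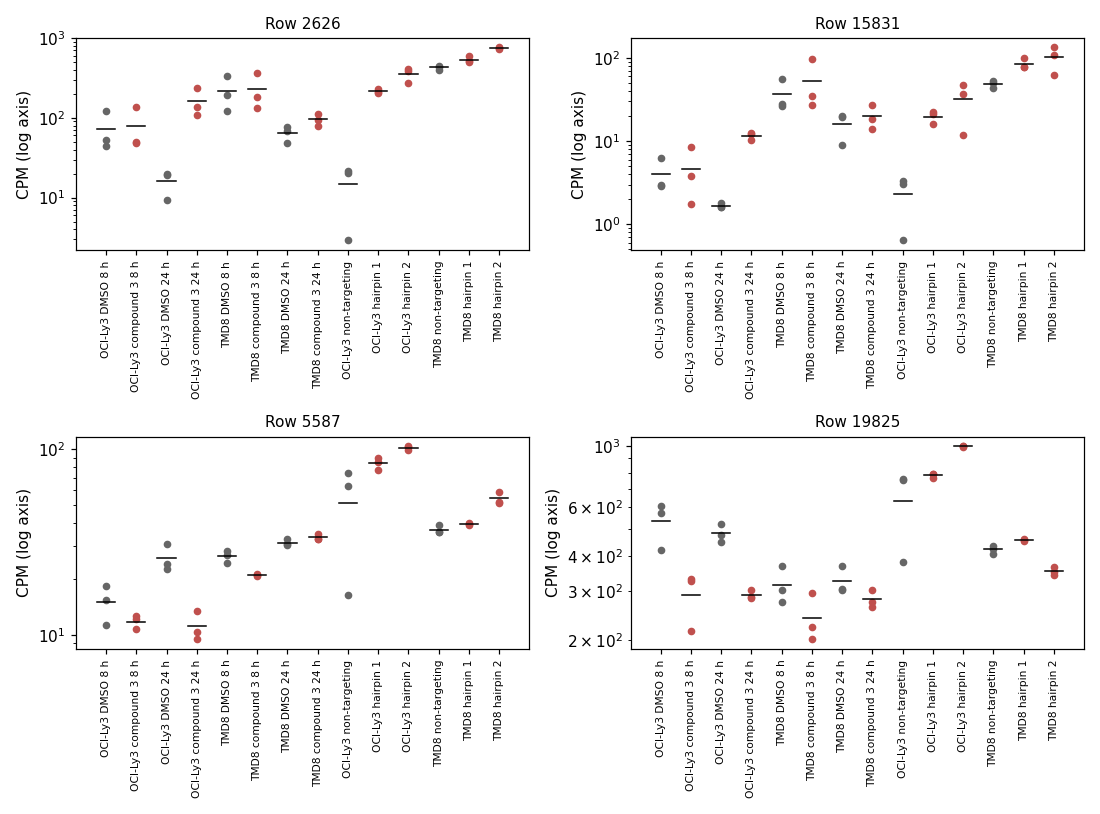
CPM of rows 2626, 15831, 5587 and 19825 in each library (points, log axis), with grey points for DMSO or the non-targeting hairpin, red points for compound 3 or a MALT1 hairpin, and a bar at the mean of each group of 3. Row 2626 rises in OCI-Ly3 from a mean of 16.0 CPM with DMSO to 160 CPM with compound 3 at 24 h, and from 15.0 CPM to 215 and 356 CPM with the hairpins.

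Whether compound 3 moves the rows that MALT1 knockdown moves was asked across the experiments, which share no library. In OCI-Ly3, 45 of the 81 rows raised by compound 3 at 24 h and tested in both were also raised by both hairpins, against 4.86 expected of independent lists, and none was lowered by both. Of the 14 lowered, 6 were lowered by both hairpins, against 0.814 expected, and 2 were raised. These 51 rows include rows 2626 and 15831. With hairpin 2 taken alone, 64 of the 81 were raised and 4 lowered. Of the 14, it lowered 7, against 3.72 expected, and raised 6. The whole set raised by both hairpins moved up with compound 3 at 24 h, by a median log2 fold change of 0.16 with 77.8% of its 722 rows above 0 (camera adjusted p = 1.08e-18 with the preset and 0.00132 with an estimated correlation). The set lowered by both moved down, by a median of -0.17 with 87.9% of its 700 rows below 0 (camera adjusted p = 1.56e-23 and 0.00408). Adjusted over the list alone, 86 of the 722 rose and 3 fell, and 6 of the 700 fell and 0 rose. In each of the 3 numbered pairs, the mean log2(CPM + 1) of the raised set was higher with compound 3, by 0.22, 0.32 and 0.19, and that of the lowered set fell by 0.17, 0.22 and 0.16. With replicates blocked in the compound experiment, 338 rows were called alike, 185 higher and 153 lower, the 51 among them. Without the block the overlap was 33 with edgeR and 82 with DESeq2 (61 higher, 21 lower). It was 16, 29 or 26 without DMSO replicate 1, 2 or 3, and 9 or 24 without compound replicate 2 or 3.

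**Figure D3:**
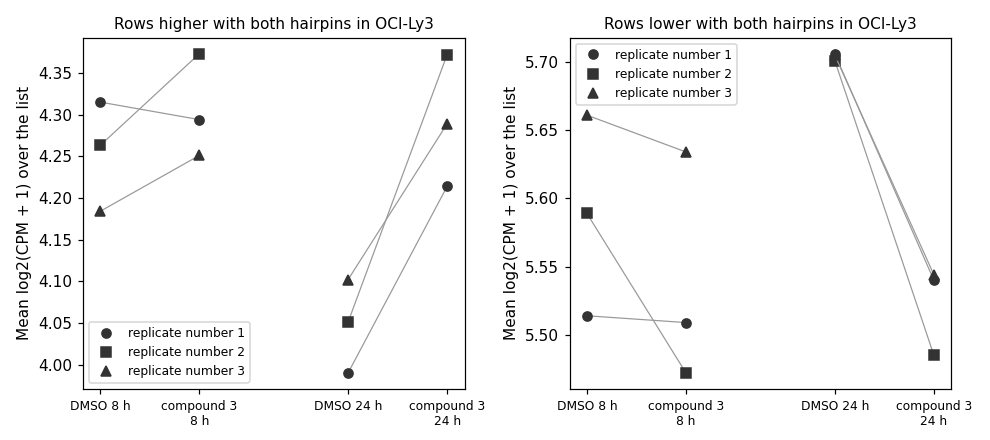
Mean log2(CPM + 1) in each OCI-Ly3 library over the rows raised by both MALT1 hairpins (left, 722 rows) and lowered by both (right, 700 rows), with lines joining DMSO and compound 3 libraries of the same replicate number. The axes do not start at 0. At 24 h the left set is higher with compound 3 in all 3 pairs and the right set lower in all 3.

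At 8 h in OCI-Ly3 the same sets had medians of 0.05 and -0.05 with compound 3. Their camera adjusted p was 0.0403 for the raised and 5.98e-07 for the lowered set with the preset correlation, and 0.343 and 0.216 with an estimated correlation. Neither call thus held with the estimated one. Across rows, the fold changes of compound 3 at 24 h in OCI-Ly3 correlated at 0.504 with those of hairpin 1 and 0.547 with those of hairpin 2. With hairpin 1 the correlation was 0.365 with edgeR, 0.371 with DESeq2 and 0.405 without OCI-Ly3 DMSO replicate 2.

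In TMD8 no row was called in the same direction with compound 3 at 24 h and with both hairpins by limma, edgeR or DESeq2, and 6 rows had an unadjusted p below 0.05 in all 3 comparisons. The 101 rows raised by both hairpins had a median log2 fold change of 0.05 with compound 3 at 24 h (camera adjusted p = 0.0236 with the preset and 0.332 with an estimated correlation). The 113 lowered rows had a median of -0.03 (camera adjusted p = 0.0571 and 0.332). The longer TMD8 sets found without OCI-Ly3 non-targeting replicate 1 were not tested. At 8 h the medians were -0.05 for the raised set (camera adjusted p = 0.0336 and 0.712), opposite to its direction in the knockdown, and -0.03 for the lowered set (camera adjusted p = 0.51 and 0.718). By fry the raised set had an adjusted p of 0.494 at 8 h, and 0.0138 with replicates blocked, where camera with an estimated correlation gave an adjusted p of 0.136. Across rows, compound 3 at 24 h correlated at 0.164 with hairpin 1 and 0.0594 with hairpin 2. The former was -0.0526 without compound 3 replicate 3 and -0.0475 without DMSO replicate 2. The latter was -0.0363 with edgeR, -0.0296 with DESeq2 and -0.023 without hairpin 2 replicate 1.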

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

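The tests of TMD8 RNA and of depth in the control library that stands apart, the test of a larger spread in TMD8, and the splits that part all numbered pairs were chosen only after the result was seen, as were the counts without that library.

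The effect of compound 3 differed between OCI-Ly3 and TMD8 by limma in 1 row at 8 h and in 3 rows at 24 h. The 8 h count was 0 without OCI-Ly3 DMSO replicate 1, OCI-Ly3 compound replicate 2 or 3, or any TMD8 library but DMSO replicate 2, and the 24 h count was 1 without OCI-Ly3 DMSO replicate 1 or 3, OCI-Ly3 compound replicate 2 or any TMD8 library. For 8 h, 19 of 100 splits of the libraries within each line called at least as many rows, so chance is not excluded, and the highest other split called 1328. That split keeps both OCI-Ly3 libraries numbered 2 and both TMD8 libraries numbered 1 in an arm, so it follows the replicate numbers. Of the 32 splits that part every numbered pair in both lines, 8 called at least 1 row and the highest other called 4, so chance is not excluded among these either. For 24 h, 10 of 100 splits called at least 3 rows and chance is not excluded. The highest other, 20 rows, exchanged the OCI-Ly3 arms whole, which adds the effects of the lines in place of subtracting them.

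The effect of hairpin 1 differed between the lines in 960 rows and that of hairpin 2 in 4920. The count of 960 was 1442 to 1778 without any 1 OCI-Ly3 control and 399 to 620 without any 1 of the other libraries. In 100 splits each, only the real one reached these counts. The splits mix hairpin and control libraries within each line and so remove the hairpin effects themselves. They therefore cannot tell a difference between the lines from a hairpin effect in either line. The highest other split for hairpin 1 called 234 rows, with the OCI-Ly3 libraries in their real arms. The highest other for hairpin 2 called 4869 and exchanged the TMD8 arms whole, so most of this count comes with the hairpin 2 change of OCI-Ly3, whichever way TMD8 is set against it.

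For compound 3 at 24 h in TMD8, limma gave 92 rows at an unadjusted p below 0.05, fewer than the share of 0.05 that unchanged rows would give. Compound 3 called 97 rows in OCI-Ly3 at 24 h (19 to 69 without any 1 of the 6 libraries) and 0 in TMD8 (also 0 by edgeR and by DESeq2), while the difference itself was called in 3 rows. The tables argue against lower depth as the cause: OCI-Ly3 reads thinned to the 25.2 M of the lowest TMD8 library called 84 to 99 rows in 5 draws. They also argue against a like change hidden by a larger spread, since the 82 raised rows had a median log2 fold change of 0.0648 in TMD8 (jackknife SE 0.025, above 0 in 59 of 82) against 0.877 in OCI-Ly3, though the latter is raised by the choice of the rows. The first form of that test was the ratio of median SDs, 1.19 for TMD8 over OCI-Ly3, which had already been seen and was replaced. A weaker response of TMD8 to the compound may be the source and stays a hypothesis, since the main test of the difference called 3 rows. With replicates blocked, 1142 rows were called in OCI-Ly3 and the difference in 261. The TMD8 24 h numbers do not pair, so the latter count is only a hint.

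OCI-Ly3 non-targeting replicate 1 was at least 2-fold off the other two controls in 865 rows with a mean of at least 5 CPM over the controls of both lines, 206 higher and 659 lower. RNA of TMD8 is argued against, since added RNA moves rows toward its source and 63% of the 865 lay on the TMD8 side, with 248 lower although TMD8 is higher. A first form of this test, on the spread of the implied TMD8 share, had 52 rows or fewer and was void. Depth is argued against by 18.4 M reads in the rows, above the 15.8 M of the lowest other OCI-Ly3 knockdown library, a hairpin library under the control label by correlations of its deviation with the hairpin changes of -0.0524 and -0.101, and a culture further along the DMSO time change by a correlation of 0.0341. The cause stays open, and no biological explanation was tested because the labels set the 3 controls alike.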

How the results depend on the processing

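The tests without OCI-Ly3 non-targeting replicate 1, without the TMD8 8 h libraries numbered 1, with the block but without the TMD8 24 h libraries, with the block across times or in the compound experiment alone, all alternatives for the DMSO time comparison and the correlations, and those of the set tests other than the estimated correlation and fry were chosen only after the result was seen. Of 936 alternative values for 55 results, 751 stayed on their side of the threshold, within 1.5 times the count or within the spread. These include counts of 0 that stayed 0. Reversal could be labelled only for single rows and set tests, where 0 called values reversed. With robust eBayes all 26 values stayed. Of the values not called, 11 changed sign: 2 of the TMD8 correlation of compound 3 with hairpin 1, 3 of that with hairpin 2, and, without a library, 3 each for rows 2626 (down to -0.423) and 15831 (down to -0.415) in OCI-Ly3 at 8 h. The cause was not tested for any value given here, except that leaving out a library leaves fewer samples and a change of filter changes the rows tested. At the depth of the TMD8 24 h libraries 69% of simulated 2-fold changes were recovered, and 25.1% of 1.5-fold ones, so small changes of single rows were often not detectable. Another scaling moved the median of all rows by at most 0.038 in size (-0.038 for hairpin 2 in OCI-Ly3).

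Without a filter, compound 3 at 8 h called 8 rows in OCI-Ly3 and 1 in TMD8, its effect differed between lines at 8 h in 2 and between times in OCI-Ly3 in 4, and the set raised by both hairpins in TMD8 had a camera adjusted p of 0.0514 with the compound at 24 h. With the stricter filter, DMSO time called 258 rows in OCI-Ly3, and the raised set of TMD8 had 0.0704 at 8 h. With a pseudocount of 0.25 the lines differed at 8 h in 0 rows, and the raised set of OCI-Ly3 had a camera adjusted p of 0.0512 at 8 h. Quantile normalization called 3 rows in OCI-Ly3 at 8 h, and the lowered set of TMD8 had 0.0315 at 24 h, against 0.0382 after median-ratio rescaling. Its other alternatives ran from 0.0149 to 0.59, those of the raised set from 0.00433 to 0.59 at 24 h and 0.0064 to 0.712 at 8 h, and those of the raised OCI-Ly3 set at 8 h from 0.0104 to 0.38.

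With edgeR, compound 3 called 2 rows in OCI-Ly3 at 8 h and 56 at 24 h, the lines differed in 0 rows at 8 h and 0 at 24 h, 33 rows were called alike with both hairpins in OCI-Ly3, and the correlations of compound 3 in OCI-Ly3 with hairpin 1 and with the TMD8 time change were 0.365 and -0.269. With DESeq2 the counts were 11 and 186, the lines differed in 0 and 11, the times in OCI-Ly3 in 21, DMSO time called 873 rows in OCI-Ly3 and 1488 in TMD8, 82 were called alike, and the correlation with hairpin 1 was 0.371. In fits of a line alone, compound 3 called 0 rows in OCI-Ly3 at 8 h and 32 at 24 h, hairpin 1 called 384 in OCI-Ly3 and 2088 in TMD8, hairpin 2 called 2707 in TMD8, and the hairpins differed in 3126 and 2012. Set tests lost their call with an estimated correlation (0.216 for the lowered and 0.343 for the raised set of OCI-Ly3 at 8 h, and 0.712 at 8 h and 0.332 at 24 h for the raised set of TMD8) and with fry (0.38, 0.38, 0.494 and 0.59).

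Without the TMD8 8 h libraries numbered 1, compound 3 called 8 rows in OCI-Ly3 at 8 h, the lines differed in 0 rows at 8 h and 1 at 24 h, and DMSO time called 977 rows in OCI-Ly3 and 359 in TMD8. Without OCI-Ly3 non-targeting replicate 1, TMD8 counts were 1953 for hairpin 1, 2810 for hairpin 2, 1994 for their difference and 951 for both, and hairpin 1 differed between lines in 1778 rows.

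With replicates blocked, compound 3 called 45 and 1142 rows in OCI-Ly3 at 8 h and 24 h and 2 in TMD8 at 8 h, the lines differed in 2 rows at 8 h, and the times in OCI-Ly3 in 179. Without the TMD8 24 h libraries these blocked counts were 63, 1516, 2, 5 and 225, with 362 called alike with both hairpins. With the block in the compound experiment alone, 338 were called alike, and across times the block called 1356 rows for DMSO in OCI-Ly3. Where the numbers pair the samples, the block also called row 19825 at 8 h, the change of rows 2626, 15831 and 5587 between times, the raised set of TMD8 at 8 h by fry (0.0138), and, in OCI-Ly3 at 24 h, the rows lowered with TMD8 time by camera with an estimated correlation (0.029) and those raised by fry (0.00491). It also called both sets of TMD8 hairpin rows in OCI-Ly3 at 24 h, by camera (0.0182 each, against 0.0539) and by fry (0.0279 each, against 0.316 for the lowered and 0.481 for the raised set), though not by camera with an estimated correlation (adjusted p = 0.232 each). There the lowered set moved up and the raised set down, opposite to the knockdown. These are 11 of 72 tests of single rows and sets compared, and no other changed its call. In TMD8 at 24 h the numbers do not pair: same-numbered libraries correlated at -0.179, -0.157 and 0.785, and 2 of 6 correlated best with their own number. DMSO replicate 1 correlated at 0.62 with compound replicate 2, and DMSO replicate 2 at 0.648 with compound replicate 1. No fit with crossed numbers was made, so their effect on the count of 0 is open. As a hint from the data, the block there called 4 rows, the lines differed at 24 h in 261, 1 row was called in all 4 compound comparisons, and the lowered set had a camera adjusted p of 0.0149, but 0.226 with an estimated correlation and 0.115 by fry. The knockdown numbers do not pair either, with at most 4 of 6 libraries best with their own number. The block gave 1534 and 6232 rows for the hairpins in OCI-Ly3 and 324 and 838 in TMD8, and 311 rows called alike with compound 3 in OCI-Ly3. For DMSO times in TMD8, where same-numbered libraries correlated at 0.158, 0.0862 and 0.39 and 6 of 6 best with their own number, it gave 2576.

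Leaving out each library gave 1 to 7 rows for compound 3 in OCI-Ly3 at 8 h and 19 to 69 at 24 h, 0 to 1 and 1 to 4 for the difference of lines at 8 h and 24 h, 0 to 1 for the difference of times in OCI-Ly3, and 70 to 635 and 175 to 1273 for DMSO time in OCI-Ly3 and TMD8. It gave 935 to 3062 for hairpin 1 in OCI-Ly3, 139 to 283 in TMD8, 526 to 731 for hairpin 2 in TMD8, 399 to 1778 for the hairpin 1 difference of lines, 285 to 542 for the difference of hairpins in TMD8, and 734 to 2389 and 89 to 192 for both hairpins in OCI-Ly3 and TMD8. The overlap of compound 3 and both hairpins in OCI-Ly3 was 9 to 58, and the correlation of compound 3 with hairpin 1 there 0.405 to 0.506. Libraries that moved these values are named with each result. The tests of MALT1 and of gene lists fixed beforehand were not run, because the rows carry no gene names.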

Other observations

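The tests of time in culture, of scaling and of a move toward the TMD8 level, the set tests with rows called between DMSO times or in the other line, and the splits that part every numbered pair at both times were chosen only after the result was seen.

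Rows that changed with time in DMSO in TMD8 moved the other way in OCI-Ly3 with compound 3 at 24 h, in libraries that share nothing with them. The 467 rows lowered between 8 h and 24 h in TMD8 had a median log2 fold change of 0.13 with the compound, and 76.9% lay above 0 (camera adjusted p = 6.41e-16 with the preset and 0.0633 with an estimated correlation). The 434 raised rows had a median of -0.10, with 76.5% below 0 (camera adjusted p = 2.01e-08 and 0.32), so neither call held with the estimated correlation without a block. With replicates blocked, the lowered set was called with an estimated correlation (camera adjusted p = 0.029) and the raised set was not (0.0569). By fry the adjusted p of the raised set was 0.00491 with the block and 0.326 without. Both sets moved the same ways with hairpin 2 in OCI-Ly3, with medians of 0.33 and -0.29 (camera adjusted p = 0.017 and 0.0121 with an estimated correlation). With hairpin 1 the medians were 0.11 and -0.13 (camera adjusted p = 0.061 and 0.0195 with an estimated correlation). With the hairpins in TMD8 itself the medians had the other sign, -0.06 and 0.05 with hairpin 1 and -0.03 and 0.04 with hairpin 2. Of these, the preset test called the lowered set with hairpin 1 (camera adjusted p = 0.000107), not with an estimated correlation (adjusted p = 0.19), and its adjusted p was 0.239 to 0.807 for the rest. In the reciprocal test, the rows that OCI-Ly3 lowered or raised with time had medians of 0.01 and 0.02 with compound 3 at 24 h in TMD8 (camera adjusted p = 0.192 each). Across rows, compound 3 at 24 h in OCI-Ly3 correlated at -0.362 with the TMD8 time change, and at -0.269 with edgeR. The time change counted 359 rows without the TMD8 8 h libraries numbered 1 and 175 without DMSO 8 h replicate 1 alone.

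Rows raised by the hairpins in TMD8 were strongly expressed and lowered rows weakly. The medians were 51.2 and 9.69 CPM for hairpin 1 and 49.5 and 12.5 CPM for hairpin 2, against 23 CPM over all rows. After rescaling, the raised and lowered rows numbered 163 and 276 for hairpin 1 in place of 247 and 233. In OCI-Ly3 the medians lay the other way, at 27.1 CPM for raised and 36.9 CPM for lowered rows with hairpin 1, and 20.8 and 41.1 CPM with hairpin 2. The rows that both hairpins moved in OCI-Ly3 had camera adjusted p of 0.319 (raised set) and 0.479 (lowered set) with compound 3 at 24 h in TMD8. At 8 h in TMD8 the raised set had a median of -0.04, opposite to the knockdown of OCI-Ly3. Its camera adjusted p was 0.0185 with the preset and 0.466 with an estimated correlation. For the lowered set at 8 h the camera adjusted p was 0.537 with the preset. Across rows, compound 3 at 24 h correlated at 0.155 between the lines, and at 0.0206 without OCI-Ly3 DMSO replicate 2.

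Compound 3 at 24 h and the hairpins moved OCI-Ly3 rows alike, with a correlation across rows of 0.547 for hairpin 2 (jackknife SE 0.152) and 51 rows called alike (16, 29 or 26 without DMSO replicate 1, 2 or 3, and 9 or 24 without compound replicate 2 or 3). With the TMD8 DMSO time change held fixed, the correlation was 0.486 (jackknife SE 0.179). This is above 0.273, which is 0.5 of the correlation and was the bound set for each test. The TMD8 time change correlated at only 0.518 with that of OCI-Ly3, so holding it fixed removes only part of the latter. Time in culture is thus not excluded as a cause. Scaling is argued against by 0.521 (jackknife SE 0.143) after quantile normalization, which replaced a first form by median-ratio rescaling that shifts the rows of a library nearly alike and was void, and the control library that stands apart by 0.48 without it. The overlap of 51 was reached by no other of 100 splits, the highest other being 43. Every other division of the OCI-Ly3 24 h compound libraries called 0 rows. A split that breaks these arms therefore had an overlap of 0 in advance, so the splits cannot exclude chance. In the reverse test, the rows raised by compound 3 at 24 h moved up with each hairpin. Their camera adjusted p with an estimated correlation was 0.0415 with hairpin 1 and 0.107, not called, with hairpin 2. For the 14 lowered rows the preset gave a camera adjusted p of 0.0318 with hairpin 1 and 0.213, not called, with hairpin 2. By fry all adjusted p were at most 8.22e-05. A shared effect of losing MALT1 activity is a candidate explanation and stays a hypothesis, because the level of MALT1 was not read and the same data gave the pattern and the tests.

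Rows 2626 and 15831, raised by compound 3 and both hairpins in OCI-Ly3, were lower there than in TMD8 in the non-targeting controls, by log2 differences of -5.11 (SE 0.44; limma adjusted p = 2.58e-08) and -4.02 (SE 0.42; limma adjusted p = 3.45e-07). The hypothesis that compound 3 moves OCI-Ly3 rows toward their TMD8 level was tested over all rows called at 24 h. Of the 97, 46 moved toward it, or 47.4%, against 51.4% of all rows, which argues against the hypothesis.

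With 3 libraries against 3, the 10 splits are too few for a share below 0.05, so only the real value and the highest other are given. For compound 3 in OCI-Ly3 these were 5 and 659 rows at 8 h, with 3 splits at or above 5, and 97 and 0 at 24 h. In TMD8 they were 0 and 924 at 8 h and 0 and 1 at 24 h, with all 10 splits at or above 0. The split with 659 keeps the pairs numbered 2 and 3 together and that with 924 the pairs numbered 1 and 2, so both follow the replicate numbers. Among the 4 splits that part all 3 pairs, the highest other called 0 rows in each of OCI-Ly3 at 8 h, OCI-Ly3 at 24 h and TMD8 at 8 h. For hairpin 1 they were 1854 and 0 in OCI-Ly3 and 480 and 0 in TMD8, and for hairpin 2 6504 and 1092 and 1051 and 0. For hairpin 2 against hairpin 1 they were 4778 and 0 and 631 and 0, and for DMSO at 24 h against 8 h 401 and 0 and 901 and 1, where only the real split, 1 of 10, reached its count.

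Of 100 splits, 2 reached the 1452 rows called with both hairpins in OCI-Ly3, the other with 3973, and only the real one, 1 of 100, reached the 219 of TMD8, with 188 as the highest other. Both high splits use the hairpin 2 libraries as control, so they hold the hairpin 2 change itself. The splits mix hairpin and control libraries and so remove the hairpin effects themselves. They argue only against hairpins without any effect. They cannot tell a shared effect from separate effects set against the same controls, so chance is not excluded for the overlap. For the change of the compound effect from 8 h to 24 h the real count was 0, which all 100 splits reach whatever they call, so they say nothing about chance. Other splits called up to 623 rows in OCI-Ly3 and 364 in TMD8, and up to 52 among the 32 that part every numbered pair in OCI-Ly3. The 623 came from 8 h arms that keep both libraries numbered 2 together, and the 364 from 8 h arms that keep the pairs numbered 1 and 2 together. All 100 splits likewise reach the counts of 0 rows called in all 4 compound comparisons and 0 rows called alike with compound 3 and both hairpins in TMD8, with 0 as the highest other.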
